A study of Homo sapiens with 6 samples.

How the data were processed

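RNA was measured in chondrocytes released by collagenase from human osteoarthritic knee cartilage, 3 libraries from preserved and 3 from damaged tissue, which the labels also call early and late osteoarthritis. Damaged replicates 1 to 3 are numbered 4 to 6 in the sample titles. Per the labels' protocols, total RNA went into libraries made with an Illumina TruSeq RNA kit. The submitters' processing notes name HISAT2 2.1.0, SAMtools 1.9, HTSeq 0.11.2, edgeR, R 4.0 and the GRCh38 genome build, with no role or order. The annotation release, the strand setting and the read layout are not given in the sources used here. Reads from overlapping or antisense genes can therefore not be separated, and a named gene that overlaps another on the same strand is marked where it is described. Named genes with an annotated gene on the opposite strand were MSMP, ABCC9, IGSF10, IGF1, RARRES1, PRG4, CDKN2A, ENPP1, VEGFA, ACTA2, MMP1, IL6, SOD2, LIF, OAS1, CYP19A1, PGR, PIEZO2, GREM1, ID2, DKK1, IGFBP7, IGFBP5, BHLHE40, PER2, PER3, IER3, NR4A1, JCHAIN, MFAP5, DPP4, PLIN4 and MMP9, besides H19, LOXL2, TIMP2, NRIP1, SLC2A1 and MCAM. The deposited values are raw counts per Ensembl gene, 1 column per library, with no normalisation by the authors.

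The table held 60617 gene rows, of which 60261 matched the gene name table and 58542 were placed on GRCh38 by GENCODE release 29. Coordinates are 1-based from that release. The summary rows that HTSeq writes for reads without a gene stayed out of library sizes and tests. They took between 20.5% and 25.0% of a library, and the part with low alignment quality took 5.98% to 10.2% of a library. Genes on chromosome Y, XIST and TSIX were left out of all tests. All 6 sample columns of the table matched a label, and no column was left unmatched.

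Damaged was compared with preserved cartilage in edgeR 4.0.16 under R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), the quasi-likelihood test and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. The design named the defaults of edgeR 4, which was read as the newer quasi-likelihood method. In the installed release the older method is still the preset of the function, and it was run as an alternative. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM are counts scaled to a library of 1e6 counts after TMM, and their errors are SD over 3 libraries. Gene lists with at least 4 tested members were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01), adjusted over the 24 lists, and medians and means of a list are on the voom log2 scale. Camera with an estimated correlation and fry were the alternatives. Library measures were compared with two-sided exact permutation tests, whose smallest possible p for 3 against 3 is 0.1. Figures were drawn in matplotlib 3.10.9.

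The groups, tests, 19 gene lists, 10 marker lists for other cell types and alternatives were fixed before the data were examined. So was the rule for the genes to be named. It took the 12 largest rises and the 12 largest falls among genes past the threshold with ranges that did not overlap and a mean CPM of at least 2. It added a fixed set (ESR1, ESR2, GPER1, SOX9, COL2A1, ACAN, PRG4, COL10A1, MMP13, COL1A1, RUNX2 and CDKN2A) and up to 4 members of each list with the smallest p. Other members of a list, when named, were chosen after their values were seen. A gene that the rule selected is not reported here.

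The alternatives fixed beforehand were a fit with the replicate number as a block, 3 other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, robust and older quasi-likelihood fits, removal of mitochondrial genes, and leaving out each library in turn. Another 3 were added after the libraries had been seen to deviate along gene GC content: removing the GC trend of each library, removing the trend within groups only, and leaving out the 2 libraries with the largest shift. GC content was available for 99.3% of tested genes.

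The procedure was tested on counts simulated from the real means and library sizes of damaged and preserved libraries, with 50 genes at each fold change among 16566. Of these, 28% were called at 1.25-fold, 66% at 1.5-fold, 84% at 2-fold and 90% at 3-fold, and 19 of 16366 unchanged genes were called. Among all genes called in this simulation, the share of unchanged genes was above the adjusted p threshold. The procedure therefore made more false calls here than that threshold aims at. Whether the same holds for the calls in the data was not tested. A list of 20 genes raised 1.5-fold was called, with 0 of 29 unchanged lists. The simulated genes varied independently, so this does not test the list calls where members of a list are correlated. A second simulation of the same comparison changed 200 of 16566 genes 1.5-fold. It put the same GC trend on preserved replicate 3 and damaged replicate 1. With the GC trend removed 154 changed genes were recovered, against 149 without removal, and 2 and 0 unchanged genes were called. Its spread was fixed below the lowest trended coefficient of variation of the data (5.74%). Log2 fold changes in the data correlated with GC content (Spearman 0.238), and removal was not tested where a GC trend differs between groups.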

Results

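Gene expression was measured by RNA sequencing in chondrocytes from human osteoarthritic knees, with cartilage sorted by macroscopic and histological grade into a preserved and a damaged group of 3 libraries each. Library totals over all rows of the table were 57899258, 47445312 and 45963151 for preserved replicates 1 to 3, and 42211930, 43075773 and 41817789 for damaged replicates 1 to 3. Counts assigned to genes ranged from 31659609 to 46017046. Preserved libraries had more of them (39417000 ± 5916700 against 32503000 ± 734070, SD, n = 3, exact two-sided permutation p = 0.1, the smallest this design allows). Mitochondrially encoded genes took 2.54% ± 0.11 of counts in preserved and 2.36% ± 0.024 in damaged libraries (SD, n = 3, exact permutation p = 0.1). The 20 most abundant genes took 17.6% ± 0.21 and 16.6% ± 0.067 (SD, n = 3, exact permutation p = 0.1).

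Within each group, 1 library stood apart along gene GC content. Preserved replicate 3 and damaged replicate 1 held fewer counts of GC-rich genes than the other libraries of their groups, by a median log2 deviation of -0.37 and -0.33 from the group mean among genes with a median GC content of 66.5%. Over 13096 genes, the chi-square per gene was 3.86 between preserved replicates 1 and 2 and 2.64 between damaged replicates 2 and 3. It was between 10.8 and 17.9 for the pairs with a shifted library. Every pair differed by more than sampling noise, so no library was a copy of another, which does not show that the libraries are independent.

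**Figure D1:**
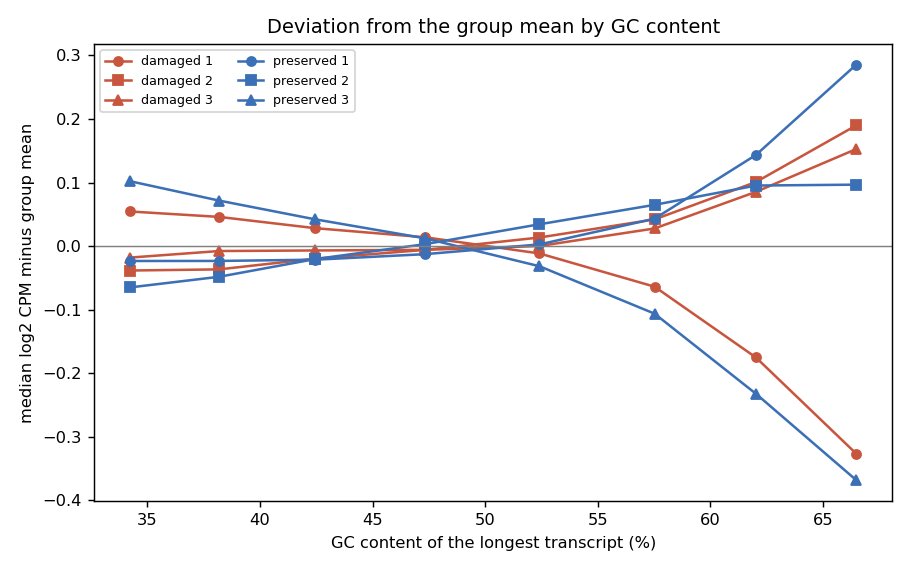
Median deviation of log2 CPM from the group mean (vertical axis) by gene GC content in percent (horizontal axis), with 1 line per library, blue for preserved and red for damaged. Preserved replicate 3 and damaged replicate 1 fall to -0.37 and -0.33 in the highest GC bin, while the other 4 libraries lie above 0 there.

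The comparison of damaged with preserved cartilage asks how the chondrocyte phenotype differs between the tissue grades, and, after the title of the series, how estrogen receptor alpha differs. ESR1, which encodes that receptor, fell from 12.2 ± 0.58 to 5.14 ± 0.27 CPM (SD, n = 3), a log2 fold change of -1.24 ± 0.08 (SE). Damaged cartilage also had more type I collagen and aggrecan transcript and less type II collagen and lubricin. COL1A1 rose from 1215 ± 282 to 4027 ± 696 CPM and ACAN, the aggrecan core protein, from 1943 ± 78.5 to 3738 ± 96.7. COL2A1, the main fibrillar collagen of hyaline cartilage, fell from 358 ± 48.4 to 192 ± 27.9, and PRG4, which encodes lubricin, from 95.3 ± 4.88 to 48.2 ± 3.54. In both groups mean COL2A1 was below COL1A2 (11641 CPM preserved, 14839 damaged), COL3A1 (7464 and 10768) and FN1 (11599 and 15949). Of the fibroblast-type matrix list to which these belong, S100A4, ACTA2, ASPN and CTHRC1 were below COL2A1 in both groups. All values come from chondrocytes released by collagenase, and whether their state changed after release was not tested.

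Of 16566 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2255 were higher and 2415 lower in damaged cartilage. At least 2-fold differences made up 486 of the rises and 372 of the falls. The ranges of the groups did not overlap for 4647 of the 4670 genes, nor for 43.3% of all tested genes, where chance gives 10%. With the GC trend within groups removed, the number of genes higher in damaged cartilage was 3683, over 1.5 times as many. That fit takes spread out of the groups but leaves any GC trend between them, so its p-values can be too small. The labels do not say whether the libraries came from separate patients, or whether the groups shared patients, so p-values measure only the spread between these samples, which may be technical (common coefficient of variation 7.21%).

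**Figure D2:**
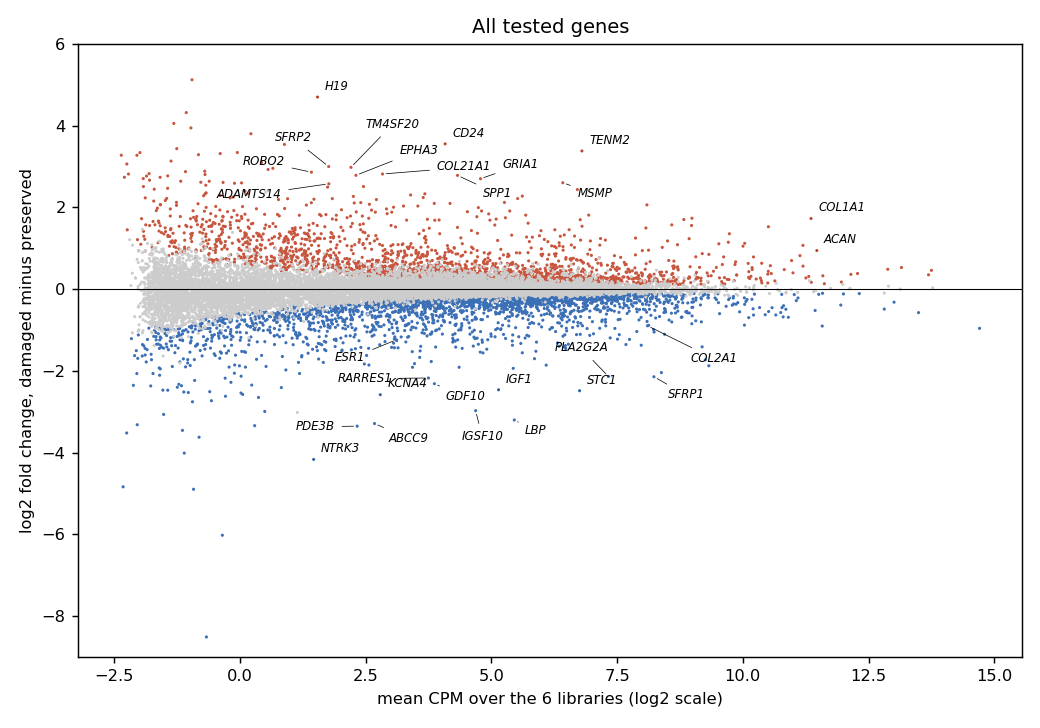
Log2 fold change, damaged minus preserved (vertical axis), against mean CPM over 6 libraries on a log2 scale (horizontal axis), 1 point per tested gene. Red and blue points are the 2255 higher and 2415 lower genes, grey points did not pass the test, and the named points are the largest changes with ESR1, ACAN, COL2A1 and COL1A1.

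ESR1 lies on GRCh38 chromosome 6 from 151656691 to 152129619 on the plus strand and overlaps AL078582.1 on the same strand. It had 541, 441 and 448 counts in preserved libraries and 175, 163 and 163 in damaged libraries, and was lower in 3 of 3 damaged libraries (edgeR quasi-likelihood test, adjusted p = 7.9e-06). ESR2, the beta receptor (chromosome 14, 64084232 to 64338112, overlapping AL161756.1), had 3 to 5 counts in every library and was below the filter, so a difference was not detectable at this depth. GPER1, a membrane estrogen receptor, was at 8.94 ± 1.57 and 6.55 ± 1.99 CPM (log2 fold change -0.45 ± 0.21, adjusted p = 0.15). It passed with the GC trend of each library removed (-0.63, adjusted p = 1.3e-03) and with both GC-shifted libraries left out (-0.36, adjusted p = 5.0e-03). With the trend within groups removed, where p-values can be too small, GPER1 also passed (-0.45, adjusted p = 0.011). Over its 20 alternatives the fold change ran from -0.63 to -0.23.

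Of 12 tested genes for estrogen receptors, cofactors and estrogen metabolism, 1 rose and 5 fell, the same counts as adjusted over the list alone. The list was lower by camera (median -0.20, adjusted p = 0.014), with an adjusted p = 0.13 with an estimated correlation. Besides ESR1, the falls included CYP19A1, the aromatase that makes estrogens (8.14 ± 0.38 to 3.93 ± 0.70 CPM), STS, steroid sulfatase (130.2 ± 5.54 to 96.4 ± 5.34), and the corepressor NRIP1 (45.3 ± 3.93 to 37.3 ± 1.47), which overlaps AF127577.4. The NRIP1 call was lost without damaged replicate 2 (log2 fold change -0.24, adjusted p = 0.074). Genes known to respond to estrogen moved both ways, with 3 of 14 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.98). PGR, the progesterone receptor, rose from 0.842 ± 0.042 to 2.43 ± 0.082 CPM and STC2 from 414 ± 26.4 to 756 ± 17.7. CXCL12 fell from 104 ± 3.85 to 50.8 ± 1.06 and CA12 from 126 ± 1.37 to 72.5 ± 1.2.

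**Figure D3:**
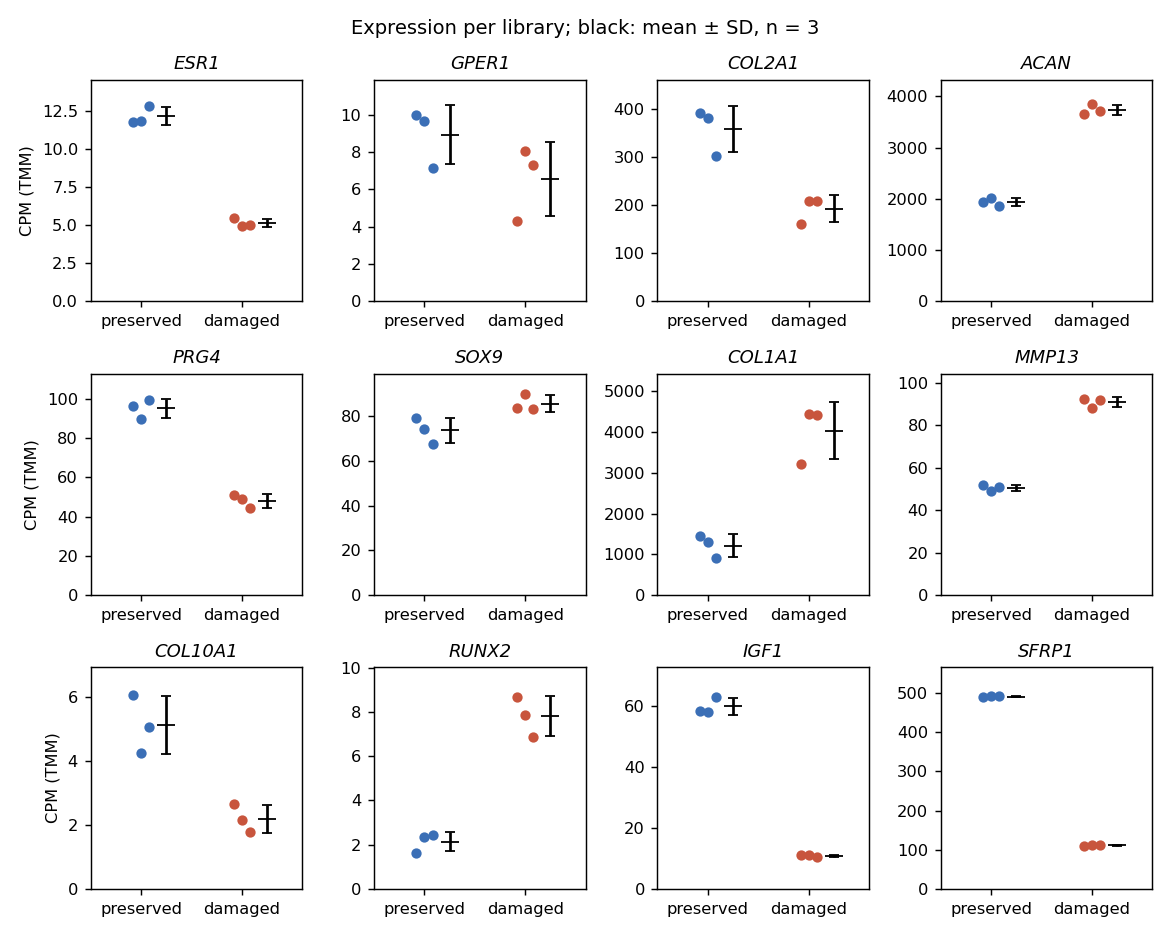
CPM per library (vertical axis, starting at 0) of 12 genes in preserved (blue) and damaged (red) cartilage, with the mean and SD of 3 libraries in black. ESR1 is near 12.2 CPM in preserved and 5.14 in damaged libraries, with no overlap, while the ranges of GPER1 overlap.

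The largest rises included TENM2, a cell adhesion protein, from 19.5 ± 0.27 to 203 ± 3.91 CPM (log2 fold change 3.38 ± 0.04, adjusted p = 1.5e-09), and CD24, a surface glycoprotein, from 2.64 ± 0.16 to 31.2 ± 1.4. SPP1, which encodes osteopontin, rose from 5.05 ± 0.86 to 35.1 ± 3.89 CPM, and MSMP from 24.3 ± 3.43 to 147 ± 4.55. Further rises were SFRP2 (3.00 on the log2 scale), TM4SF20 (2.98), ROBO2 (2.86), COL21A1 (2.82), EPHA3 (2.79), the glutamate receptor subunit GRIA1 (2.70) and the procollagen peptidase ADAMTS14 (2.58). The noncoding RNA H19 had the largest fold change (4.70 ± 1.02), yet its damaged libraries spread widely, at 7.29, 0.639 and 8.92 CPM. Its adjusted p was 9.1e-03 in the edgeR test, and the call was lost in the robust quasi-likelihood fit (0.062) and in limma-voom (0.13), over a range of log2 fold changes from 4.00 to 5.24, and it overlaps MIR675.

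Among the falls, the growth factor IGF1 went from 59.8 ± 2.82 to 10.8 ± 0.35 CPM (log2 fold change -2.47 ± 0.06, adjusted p = 3.2e-08). SFRP1, a secreted Wnt inhibitor, fell from 490.6 ± 2.08 to 110.8 ± 1.45 CPM, and STC1, which encodes stanniocalcin, from 183 ± 4.73 to 32.6 ± 0.22. PLA2G2A, a secreted phospholipase, fell from 262 ± 10.9 to 59.5 ± 2.19 CPM, and LBP, the lipopolysaccharide-binding protein, from 79.2 ± 3.20 to 8.59 ± 0.82. The neurotrophin receptor NTRK3 changed by -4.17 on the log2 scale, PDE3B by -3.35, ABCC9 by -3.29, IGSF10 by -2.98, the potassium channel KCNA4 by -2.59, GDF10 by -2.32 and RARRES1 by -2.18.

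Genes of cartilage matrix and chondrocyte identity split, with 7 of 25 higher and 11 lower (9 and 13 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.38). Alongside ACAN, the rises held MATN3 (22.8 ± 1.6 to 80.0 ± 2.93 CPM) and COL11A1 (1203 ± 20.1 to 1789 ± 27.2). With COL2A1 and PRG4, the falls held CYTL1 (42.6 ± 1.10 to 14.4 ± 0.68 CPM). SOX9, the transcription factor of the chondrocyte lineage, was at 73.6 ± 5.80 and 85.5 ± 3.85 CPM (log2 fold change 0.22 ± 0.06, adjusted p = 0.033). The SOX9 call was lost in 4 of the 6 fits that left out a library, with log2 fold changes from 0.16 to 0.27 over all alternatives: without preserved replicate 2 (adjusted p = 0.080), preserved replicate 3 (0.054), damaged replicate 2 (0.11) and damaged replicate 3 (0.070).

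Fibroblast-type matrix genes were higher as a list, with 17 of 22 rising and 2 falling, the same adjusted over the list alone (median 0.38, camera adjusted p = 2.3e-09, and adjusted p = 0.13 with an estimated correlation). The smooth muscle actin gene ACTA2 rose from 54.3 ± 2.30 to 191 ± 2.62 CPM, periostin (POSTN) from 479 ± 20.2 to 1224 ± 39.2, S100A4 from 58.3 ± 4.31 to 143 ± 1.51 and LOXL2, a collagen cross-linking enzyme, from 291 ± 21.2 to 685 ± 32.8. LOXL2 overlaps ENTPD4. The lowest COL1A1 value of each group came from the GC-shifted library, at 903 CPM in preserved replicate 3 and 3223 CPM in damaged replicate 1. In the hypertrophy and mineralisation list 6 of 12 rose and 2 fell (6 and 3 adjusted over the list alone), and the list test did not pass (camera adjusted p = 0.078). RUNX2, a transcription factor of hypertrophy and bone, rose from 2.14 ± 0.44 to 7.80 ± 0.91 CPM and VEGFA from 304 ± 10.4 to 488 ± 13.3. COL10A1, the collagen of hypertrophic cartilage, fell from 5.14 ± 0.92 to 2.20 ± 0.43, and ENPP1 from 186 ± 5.10 to 107 ± 2.02.

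Matrix-degrading proteases went both ways, with 7 of 20 higher and 9 lower (8 and 10 adjusted over the list alone, camera adjusted p = 0.27). Their median was -0.18 (-0.29 without preserved replicate 3) and their mean 0.0045, opposite in sign. MMP13, the collagenase of cartilage, rose from 50.6 ± 1.44 to 90.8 ± 2.32 CPM. MMP1 fell from 121 ± 3.75 to 59.6 ± 3.09 CPM, ADAMTS1 from 1692 ± 0.56 to 1096 ± 0.60 and CTSK, cathepsin K, from 311 ± 9.46 to 193 ± 4.93. Of 13 protease inhibitors, 2 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.079). SERPINA1 fell from 114 ± 4.68 to 45.7 ± 1.43 CPM, and SERPINE2 and TIMP2 fell. TIMP2 overlaps CEP295NL.

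Inflammatory genes were mixed, with 8 of 19 higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.56). IL6 fell from 27.5 ± 0.88 to 11.4 ± 0.57 CPM, TNFAIP6 from 131 ± 2.68 to 47.7 ± 2.69 and SOD2 from 363 ± 15.5 to 196 ± 12.6, and LIF rose from 12.5 ± 1.28 to 24 ± 0.68. SOD2 overlaps another gene entry of the same name. Interferon response genes were lower, with 13 of 20 falling and 1 rising (14 and 1 adjusted over the list alone, median -0.48, camera adjusted p = 9.5e-06, and adjusted p = 0.10 with an estimated correlation). OAS1 fell from 6.85 ± 0.086 to 2.44 ± 0.13 CPM, IFI44 from 14.1 ± 0.54 to 7.05 ± 0.33, GBP2 from 77.6 ± 2.64 to 49.8 ± 1.53 and IFI6 from 48.4 ± 2.36 to 29.4 ± 1.75. GBP2 overlaps GBP7.

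Mechanosensor and cell-matrix adhesion genes were higher as a list, with 13 of 25 rising and 4 falling (14 and 4 adjusted over the list alone, median 0.21, camera adjusted p = 2.6e-03, and adjusted p = 0.13 with an estimated correlation). CAV1, which encodes caveolin, rose from 93.4 ± 4.58 to 215 ± 5.62 CPM, the stretch-gated potassium channel KCNK2 from 13.2 ± 0.90 to 35.5 ± 0.94 and the collagen receptor subunit ITGA11 from 1530 ± 51.5 to 2481 ± 22.1. The mechanically gated channel PIEZO2 fell from 284 ± 3.72 to 193 ± 0.72 CPM. Target genes of YAP and TAZ moved both ways (5 of 23 higher, 7 lower, or 5 and 8 adjusted over the list alone, camera adjusted p = 0.92). MYOF rose from 499 ± 4.64 to 604 ± 7.23 CPM, NUAK2 and TGFB2 rose too, and DOCK5 fell from 103 ± 5.35 to 82.8 ± 3.72. TGFB2 overlaps TGFB2-OT1.

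In TGF-beta and BMP signalling 8 of 26 rose and 10 fell (9 and 10 adjusted over the list alone, camera adjusted p = 0.48). The BMP antagonist GREM1 rose from 213 ± 6.36 to 695 ± 17.9 CPM, and BMP2 (34.9 ± 0.91 to 15.4 ± 0.43), TGFBR3 (84.7 ± 3.09 to 34.5 ± 1.16) and ID2 (185 ± 1.18 to 109.8 ± 1.15) fell. Wnt signalling genes counted 6 of 18 higher and 5 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.61). Besides the fall of SFRP1, DKK3 rose from 85.8 ± 2.23 to 202 ± 5.45 CPM, WNT5A from 33.0 ± 0.86 to 79.6 ± 1.12 and DKK1, a Wnt antagonist, from 2.54 ± 0.066 to 9.73 ± 0.23.

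Cell cycle genes rose together, in 20 of 21 cases with none falling, the same adjusted over the list alone (median 0.85, camera adjusted p = 1.5e-11, and adjusted p = 0.10 with an estimated correlation). MKI67 rose from 7.85 ± 0.66 to 18.2 ± 0.60 CPM, TOP2A from 17.0 ± 0.47 to 31.5 ± 1.28, RRM2 from 6.00 ± 0.42 to 12.9 ± 1.52 and BIRC5 from 2.06 ± 0.25 to 4.92 ± 0.24. RRM2 overlaps AC007240.1. In the senescence and p53 list 9 of 17 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.014, and adjusted p = 0.18 with an estimated correlation). CDKN2A, an inhibitor of cell cycle kinases, rose from 0.978 ± 0.28 to 2.15 ± 0.30 CPM, CDKN2B from 6.82 ± 0.74 to 12.6 ± 0.79 and IGFBP7 from 267 ± 2.20 to 566 ± 16.7. IGFBP5 fell from 3989 ± 98.5 to 2131 ± 69.0.

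Hypoxia and glycolysis genes were modestly higher, with 12 of 21 rising and 2 falling (13 and 3 adjusted over the list alone, median 0.16, camera adjusted p = 7.1e-03, and adjusted p = 0.13 with an estimated correlation). Next to VEGFA, the glucose transporter SLC2A1 rose from 109 ± 7.45 to 146 ± 2.86 CPM, PGK1 from 587 ± 26.1 to 736 ± 18.6 and PFKFB4 from 10.6 ± 0.74 to 16.8 ± 1.13. SLC2A1 overlaps AC099795.1, PGK1 overlaps ATP7A, and PFKFB4 overlaps UCN2. Antioxidant and metal response genes were lower, with 9 of 21 falling and 2 rising, the same adjusted over the list alone (median -0.25, camera adjusted p = 0.040, and adjusted p = 0.16 with an estimated correlation). GPX3, an extracellular glutathione peroxidase, fell from 536 ± 17.2 to 130.1 ± 4.50 CPM, HMOX1 from 465 ± 32.0 to 353 ± 21.9 and FOXO3 from 107 ± 0.38 to 83.8 ± 3.37. This call was lost without preserved replicate 2 (median -0.18, adjusted p = 0.051) and under the stricter filter (-0.22, 0.085). The median was -0.15 without preserved replicate 1 and -0.17 without damaged replicate 1.

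Circadian clock genes counted 5 of 16 higher and 1 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.21), with BHLHE40 at 148 ± 4.93 and 214 ± 5.05 CPM, PER2 and PER3 higher and NFIL3 lower. Immediate early and heat shock genes, which can respond to tissue handling, counted 5 of 19 higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.23). FOSB rose from 319 ± 30.8 to 473 ± 27.9 CPM, IER3 and NR4A1 rose, and BTG2 fell.

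**Figure D4:**
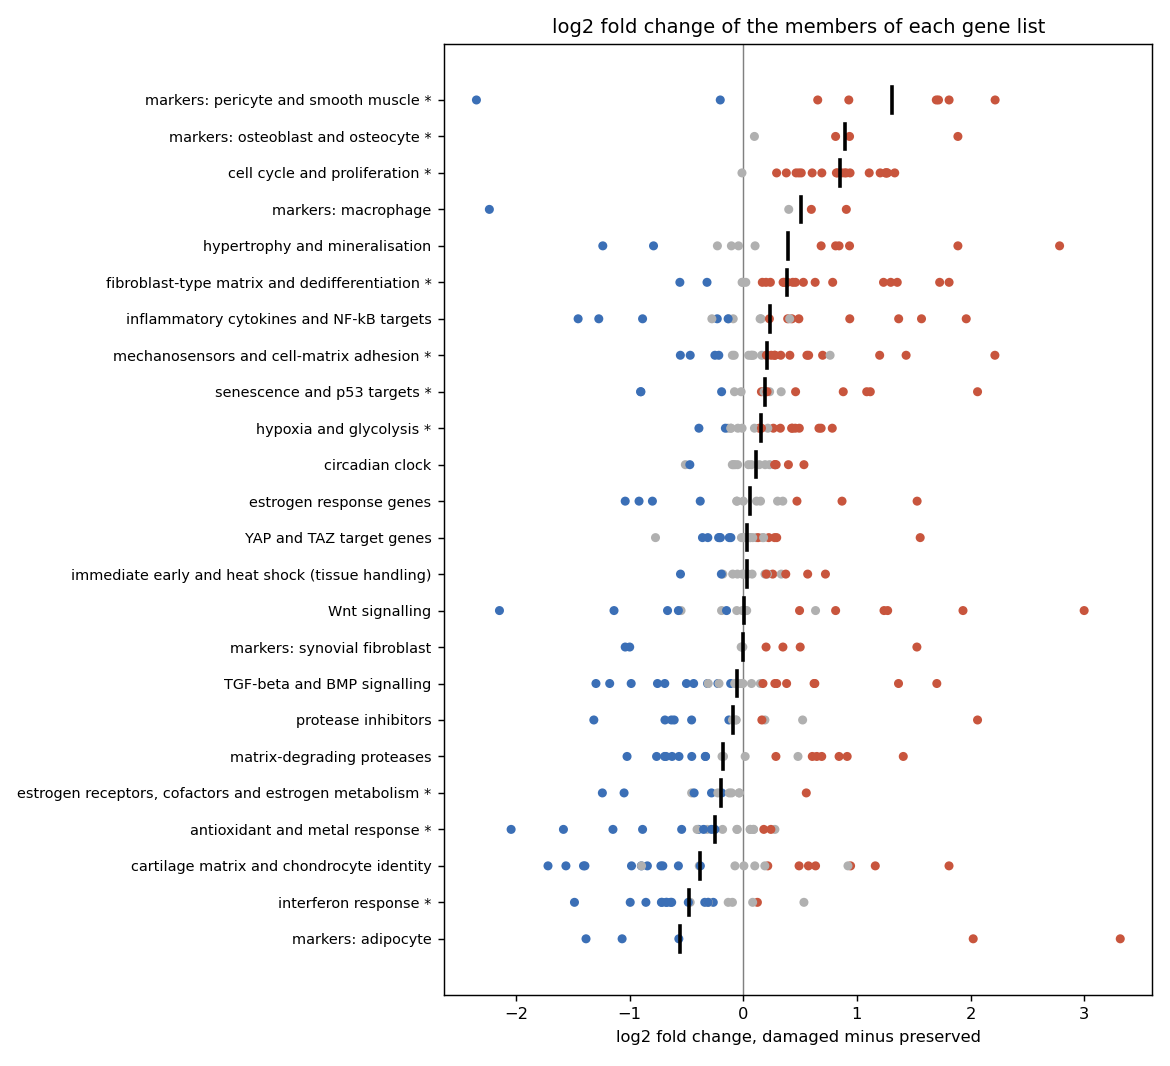
Log2 fold change, damaged minus preserved (horizontal axis), of each tested member of the 24 gene lists (rows, with marker lists named as such). Red members rose, blue members fell, grey members did not pass the test, black bars are medians, and the asterisks mark the 10 lists called by camera with a preset correlation, none of which held with an estimated correlation.

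Markers of other cell types were examined beside these groups. Pericyte and smooth muscle markers were higher as a list, with 6 of 8 rising and 2 falling, the same adjusted over the list alone (median 1.31, camera adjusted p = 2.9e-03, and adjusted p = 0.13 with an estimated correlation). All 8 were detected in preserved cartilage as well, and ACTA2 also stands in the fibroblast list. RGS5 rose from 16.3 ± 1.94 to 75.6 ± 3.24 CPM, NOTCH3 from 51.2 ± 10.6 to 167 ± 26.9 and MCAM from 6.33 ± 0.28 to 12 ± 0.61, while KCNJ8 fell from 1.97 ± 0.34 to 0.379 ± 0.075. MCAM overlaps MIR6756, and RGS5 overlaps another gene entry of the same name. Osteoblast and osteocyte markers were higher, with 3 of 4 rising and none falling, the same adjusted over the list alone (median 0.89, camera adjusted p = 0.014, and adjusted p = 0.13 with an estimated correlation). These were RUNX2, ALPL (29.6 ± 2.91 to 52.0 ± 4.47 CPM) and IBSP (6.58 ± 2.11 to 12.7 ± 1.10). All 4 were detected in preserved cartilage and 3 also belong to the hypertrophy list, and PHEX was at 1.92 ± 0.22 and 2.05 ± 0.37 CPM. The other members of this list were below the filter. Over all 6 libraries SP7 had 24 counts, MEPE 11, BGLAP 2, DMP1 0 and SOST 0.

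Synovial fibroblast markers counted 4 of 9 higher and 2 lower (camera adjusted p = 0.45), with a median of -0.0026 (0.036 without preserved replicate 3) against a mean of 0.056 and an upward test. MFAP5 rose from 2.39 ± 0.30 to 6.85 ± 0.62 CPM, and GAS1 and DPP4 rose. Macrophage markers had 2 of 4 higher and 1 lower (camera adjusted p = 0.63, median 0.51 and mean -0.090). HLA-DRA, an antigen-presenting molecule, fell from 0.887 ± 0.17 to 0.185 ± 0.082 CPM, and CD14 rose from 12.1 ± 2.67 to 18.4 ± 2.93 and MRC1 from 0.290 ± 0.051 to 0.543 ± 0.12. The CD14 call was lost in the robust fit (log2 fold change 0.60, adjusted p = 0.071) and without preserved replicate 2 (0.67, 0.0501), damaged replicate 2 (0.52, 0.080) or damaged replicate 3 (0.55, 0.10). The MRC1 call was lost in DESeq2 (0.91, 0.22), in limma-voom (0.88, 0.054) and without the filter (0.91, 0.073). It was also lost without preserved replicate 1 (0.89, 0.11), 2 (0.80, 0.12) or 3 (1.03, 0.055) and without damaged replicate 2 (0.78, 0.16) or 3 (0.85, 0.13). Adipocyte markers had 2 of 5 higher and 3 lower (camera adjusted p = 0.87, median -0.56 and mean 0.46). LEP rose from 0.140 ± 0.051 to 1.38 ± 0.43 CPM and LPL from 0.284 ± 0.039 to 1.15 ± 0.031, and FABP4 and PLIN4 fell. The counts adjusted over the list alone were the same for these 3 lists.

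Another 5 marker lists had fewer than 4 members above the filter and were not tested as lists. Among endothelial markers TEK rose from 0.628 ± 0.23 to 2.18 ± 0.40 CPM, ERG fell from 115 ± 1.66 to 66.1 ± 0.76, and EGFL7 was at 4.75 ± 1.37 and 5.66 ± 1.69. PECAM1, VWF, CDH5 and CLDN5 of the same list summed to 0.135 to 0.530 CPM per library. The fall of ERG is therefore not read as a loss of endothelial cells. In the osteoclast list MMP9 rose and CTSK fell, with OSCAR at 0.726 ± 0.26 and 0.595 ± 0.045 CPM. For T, B and plasma cells, IL7R rose from 11.8 ± 0.86 to 19.8 ± 0.35 CPM and JCHAIN was at 4.89 ± 0.47 and 3.89 ± 0.46, with 1 of 2 tested genes higher and 0 lower (1 and 1 adjusted over the list alone). JCHAIN passed only with the GC trend within groups removed (log2 fold change -0.33, adjusted p = 0.035), a fit whose p-values can be too small. Among neutrophil and marrow markers, ELANE alone was tested, at 0.632 ± 0.24 and 0.790 ± 0.20 CPM. Of the erythroid list 0 of 8 genes passed the filter, and HBB and HBA2 had 0 counts in all 6 libraries. PTPRC, a general leukocyte gene, had 2 counts in damaged replicate 2 and 0 in every other library. The levels of IL7R and CD14 are therefore not read as leukocyte content.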

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

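ESR1 stayed lower and past the threshold under all 20 alternatives, with log2 fold changes between -1.29 and -1.20. Under other scalings, filters, tools and dispersion fits, the numbers of higher and lower genes lay within 1.5 times 2255 and 2415. Leaving out 1 library gave 1538 (without damaged replicate 3) to 2501 (without damaged replicate 1) higher genes, 1641 (without damaged replicate 2) to 2298 (without preserved replicate 3) lower genes, and 9 to 12 called lists. The exception, chosen after seeing the data, was 3683 genes higher in damaged cartilage with the GC trend within groups removed, 2253 of them shared with the 2255. The p-values of that fit can be too small, since it lowers the spread within groups only. The cause was not tested beyond that removal. Camera called 10 lists, 0 with an estimated correlation, with a lowest adjusted p of 0.10, and fry, which does not compare a list with other genes, called 16. A replicate block gave 1585 higher genes, 1739 lower genes and 10 lists, and among named genes SOX9 (adjusted p = 0.055), CD14 (0.068) and MRC1 (0.091) did not pass in it. Deviations of same-numbered libraries correlated at -0.24, 0.10 and -0.15, and those of preserved replicate 3 and damaged replicate 1, both GC-shifted, at 0.32. The numbers were therefore not used as pairs, which leaves open whether the groups shared patients.

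Directions reversed only for results that had not passed. With the GC trend of each library removed these were ELANE (-0.044), EGFL7 (-0.14) and the estrogen response list (median -0.016). Fry turned the direction of the inflammatory (median 0.23), estrogen response (0.058) and adipocyte (-0.56) lists. The stricter filter turned the estrogen response (-0.00644) and adipocyte (0.71) lists, and leaving out both GC-shifted libraries turned the test of the YAP and TAZ list (0.029). Leaving out 1 library gave -0.015 to 0.23 for PHEX, -0.48 to 0.061 for OSCAR, 0.045 to 0.15 for the estrogen response list and 0.0046 to 0.054 for the YAP and TAZ list. The cause of these turns was not tested. Depth limits genes such as ESR2, with 3 to 5 counts per library.

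With an estimated correlation the calls of 10 lists were lost, with medians unchanged: fibroblast-type matrix 0.384, interferon -0.481, estrogen receptors and metabolism -0.195, mechanosensors 0.210, cell cycle 0.855, senescence 0.191, hypoxia 0.160, antioxidant -0.251, pericyte and smooth muscle 1.31, osteoblast 0.893. The estimate was below the preset 0.01 for interferon (-0.040), estrogen receptors (-0.019), hypoxia (-0.012), antioxidant (-0.024), pericyte (-0.0050) and osteoblast (-0.11) lists. It was 0.026 to 0.16 for the other called lists. Correlated members therefore do not account for the loss in the lists below the preset. The fit has 4 residual degrees of freedom, and their part in the loss was not tested. The antioxidant list was also lost under the stricter filter (-0.222) and ran from -0.248 to -0.154 with 1 library left out. Fry called the hypertrophy (0.394), protease (-0.177), inhibitor (-0.0946), TGF-beta and BMP (-0.0520) and circadian (0.108) lists, and the inflammatory list as lower (adjusted p = 0.015) against its positive median. Leaving out both GC-shifted libraries called the hypertrophy (0.369), protease (-0.305) and inhibitor (-0.102) lists. With 1 library left out, hypertrophy ran from 0.354 to 0.424 and inhibitors from -0.119 to -0.0811, and either was called in some of these fits. Medians of other lists that had not passed moved by over 1.5 times, to -0.290 for proteases and -0.126 for TGF-beta and BMP without preserved replicate 3, 0.122 for the inflammatory list without preserved replicate 2, 0.173 for the circadian list without damaged replicate 1 and 0.0671 for the immediate early list without preserved replicate 1. The Wnt median of 0.0063 changed sign without preserved replicate 3 (-0.0528), damaged replicate 1 (-0.000912), damaged replicate 2 (-0.0212) or damaged replicate 3 (-0.0315). The cartilage matrix median moved from -0.378 to -0.118 without preserved replicate 1 and -0.112 without damaged replicate 1.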

Other observations

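The gene families below, and every test in this part except the split and depth tests of the number of changed genes, were chosen after results had been seen, the GC test of that number after the libraries had been seen to deviate along GC content. Collagens, a family that includes members of the fixed lists, were mostly higher in damaged cartilage, with 20 of 34 rising and 6 falling (median log2 fold change 0.48, camera adjusted p = 1.5e-05, and adjusted p = 0.26 with an estimated correlation). COL8A1 rose from 751 ± 18.7 to 2163 ± 40.7 CPM (SD, n = 3), and the basement membrane chains COL4A1 from 138 ± 5.49 to 329 ± 8.62 and COL4A2 from 222 ± 33.6 to 503 ± 53.7. Keratins rose in 8 of 9 cases under a second definition without KRT10-AS1, an antisense RNA that the first had taken in (camera adjusted p = 3.8e-05, and adjusted p = 0.21 with an estimated correlation), from low levels, with KRT7 at 3.72 ± 0.67 and 9.30 ± 1.61 CPM. Tubulins and their partners rose in 10 of 17 cases with none falling (camera adjusted p = 6.5e-05, and adjusted p = 0.26 with an estimated correlation), with a median of 0.30 that was 0.15 with the GC trend of each library removed. The second definition, without the partners, gave 10 of 12 rising (camera adjusted p = 1.1e-06, and adjusted p = 0.21 with an estimated correlation), with a median of 0.42 that was 0.31 after that removal. TUBB rose from 582 ± 13.5 to 840 ± 22.7 and TUBA1B from 213 ± 9.22 to 328 ± 10.4 CPM. Genes of cholesterol synthesis and its regulation fell in 10 of 17 cases with none rising (camera adjusted p = 1.3e-04, and adjusted p = 0.20 with an estimated correlation), INSIG1 from 188 ± 3.59 to 96.8 ± 3.90 CPM.

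Complement genes were lower, with 10 of 24 falling and 1 rising (camera adjusted p = 3.1e-03, and adjusted p = 0.21 with an estimated correlation). The first definition of this family, made from symbols, had taken in relatives outside the pathway, such as C1QTNF1. A second definition, drawn after the first result and with regulators added, gave 14 of 20 falling and 1 rising (adjusted p = 1.1e-07, and adjusted p = 0.054 with an estimated correlation), so this p-value is not independent of the data. C3 fell from 21.6 ± 2.1 to 8.10 ± 0.022 CPM, C1S from 2168 ± 40.6 to 1540 ± 8.74 and SERPING1 from 735 ± 27.8 to 422 ± 6.72. Mitochondrial complex subunits encoded in the nucleus rose in 26 of 72 cases with none falling (median 0.15, camera adjusted p = 9.7e-07, and adjusted p = 0.26 with an estimated correlation). The genes encoded in mitochondria fell in 8 of 13 cases with none rising (median -0.17, camera adjusted p = 6.1e-05, and adjusted p = 0.26 with an estimated correlation), MT-ND2 from 916 ± 31.3 to 767 ± 5.56 CPM. Of the replication-dependent histones, 0 of 12 rose and 4 fell (median -0.23, camera adjusted p = 0.23). Their share of counts was 0.00684% ± 0.00018 in preserved and 0.00601% ± 0.00015 in damaged libraries (SD, n = 3, exact permutation p = 0.1). With a share this small, most of their transcript may not have been captured, so the family cannot be set against the cell cycle genes. In all, 17 families were tested under each of the 2 definitions, 6 of them redrawn, and 10 were called each time, with 0 called under an estimated correlation.

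The first pattern weighed is the number of changed genes, 4670. Among the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Every other split mixes the groups, so few calls are likely there whatever the cause of the difference. Removing the GC trend of each library left 6252 called genes, which argues against that trend as the whole cause. The removal can also lower the spread within groups, so this count does not show how many of the 4670 calls depended on GC. Over genes, the log2 fold change correlated with GC content at a Spearman value of 0.238 before that removal and -0.0016 after it. Thinning every library to the smallest total left 93.8% of the called genes called in the same direction, which argues against depth. Differences between the cartilage grades, and differences between patients that the labels do not give, both stay open and untested.

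The second is that preserved replicate 3 and damaged replicate 1 stood apart from their groups. Removing the GC trend within groups lowered their mean chi-square per gene against the other libraries of their groups by 61.4%, so a GC-dependent step in library preparation or sequencing may account for most of the gap. Lower depth is not enough, since after thinning to equal totals the chi-square of these pairs was still 4.23 times that of the other pairs. Preserved replicate 3 had 9.62% of its library at low alignment quality, against 5.98% and 6.43% in preserved replicates 1 and 2. Damaged replicate 1 had 10.2%, against 9.19% and 8.13% in damaged replicates 2 and 3. The labels do not say whether libraries of a group came from separate patients. A difference between patients within a group therefore stays open, and no biological explanation was tested.

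The third is the rise of pericyte and smooth muscle markers in damaged cartilage. PECAM1, VWF, CDH5 and CLDN5 together reached at most 0.893% of the rise in RGS5 (59.3 CPM). They had 5 to 17 counts per library, which argues against vessel tissue that kept its endothelial cells. MYH11, abundant in smooth muscle cells, reached at most 0.201% of the rise in ACTA2 (136 CPM), which argues against smooth muscle cells that kept MYH11. Whether cells changed after release was not tested, so vessel wall cells without these transcripts stay open. Pericytes cannot be told apart from chondrocytes that express the markers that rose. The reason is that KCNJ8 changed by -2.35 on the log2 scale, and a loss in chondrocytes could hide pericyte transcript.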
